A study of Mus musculus with 24 samples.

How the data were processed

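Total RNA of mouse triceps surae muscle had been labelled as biotinylated cRNA and hybridized to Illumina mouse beadchips, per the labels. The 24 arrays fell into 8 groups of 3 by genotype (wild type or MuRF1 knockout), treatment (none or dexamethasone) and time (3 or 14 days). The labels name separate samples but not whether these are separate animals, so p-values here measure the spread between these samples, which may be technical. BeadStudio 3.2.3 is named per the submitters' processing notes, which do not give its role.

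A deposited table of non-normalized values gave, per the file headers, an average signal intensity of each of 46632 probes on each array. The same deposited table gave a detection p-value for each probe and array, per the file headers. A second deposited table, the authors' value table, held linear intensity values that were background-subtracted and quantile-normalized, as read from the values themselves, and it served only as an alternative with a floor at 16. No column lacked a sample. Replicate numbers in the text are those of the non-normalized table, which differ from those of the value table in 5 groups. The beadchip identifiers, scanner settings and the authors' own tests are not given in the sources used here.

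Signals were background-corrected with the detection p-values, quantile-normalized and put on the log2 scale with an offset of 16 by the neqc method of limma 3.58.1 in R 4.3.3. A probe was kept when its detection p was under 0.05 on at least 3 of the 24 arrays, which left 20769 probes. The probe annotation gave 1 symbol for 29976 of all probes, several for 10 and none for 16646. Of the kept probes 15517 had 1 symbol. Each of the 3303 genes with several kept probes was represented by its probe of highest mean signal, and unnamed probes were kept singly, giving 16262 features, 11010 of them named genes. Symbols were compared with RefSeq names of GRCm38.p6, which updated 0 of them. That table was used for names and gene order only. A fold change past the threshold between groups of arrays is given as a lower bound where no array of the lower group detected the probe.

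A linear model with a mean for each of the 8 groups was fitted in limma to log2 values, with 16 residual degrees of freedom and moderated standard errors. Dexamethasone was compared with no treatment within each genotype and time, knockout with wild type within each treatment and time, and the differences between genotypes and between times of the dexamethasone effect were tested as interactions. Adjusted p values are those of Benjamini and Hochberg within each comparison, with a threshold of 0.05. Errors after ± are standard deviations of 3 arrays, and SE is the standard error of a log2 fold change.

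Before the data were examined, 33 gene lists were fixed. They cover glucocorticoid-responsive genes, atrophy-linked ubiquitin ligases, the proteasome, autophagy, insulin and myostatin signalling, slow and fast fibres, glycolysis, lipid handling, oxidative phosphorylation, the neuromuscular junction, extracellular matrix, amino acids, clock genes, oxidative stress, heat shock, interferon and antigen presentation, inflammatory cytokines, calcium handling and the cell cycle. The others hold markers of adipocytes, endothelium, macrophages, lymphocytes, neutrophils, red blood cells, Schwann cells, satellite cells, fibroblasts, tendon, smooth muscle and sex. Lists with at least 5 measured members, 32 of them, were tested with camera at an inter-gene correlation of 0.01 and again with the correlation estimated from the arrays, and p values were adjusted across lists. Members were also counted past the threshold after adjustment over the list alone.

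The genes to name were chosen by a rule fixed at the same time. Trim63 was named in every comparison. In each dexamethasone comparison the 10 genes per direction with the largest change were taken among those past the threshold whose arrays did not overlap between groups, and in each genotype comparison 6 per direction. In each interaction 6 genes per direction were taken by size of change, and from each list up to 4 members. Clone names and predicted genes were passed over, and some genes are left unnamed for length. Of 422 named results past the threshold, 154 had another kept probe, 77 of these with another probe past the threshold in the same direction, and 0 with one past it in the opposite direction. No other kept probe passed in the same direction, in at least one comparison that names the gene, for Angptl4, Aqp4, Bmp1, Cblb, Cd74, Eif4ebp1, Fn1, Foxo1, Fstl1, Hectd2, Hyi, Il6ra, Myoz2, Pnpla2, Prodh, Psmd4, Rbp7, Ripply3, Smtn, Stc2, Sypl2 and Xirp2, so these calls rest on single probes. Calls of genes with no other kept probe also rest on single probes.

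The model was tested on simulated data of 16262 genes and 24 arrays with 100 genes changed 1.5-fold and 100 changed 2-fold. For a dexamethasone comparison 29% and 73% were recovered with 3 false calls, for a genotype comparison 25% and 82% with 4, for an interaction with genotype 8% and 35% with 1, and for an interaction with time 1% and 18% with 0. Of 32 simulated lists, the 2 that had been shifted were called and 0 others. Simulated genes varied independently of each other, so this does not show how often correlated lists would be called falsely. Alternatives tried were arrays scaled on their 75th percentile, no background correction, the authors' value table, no detection filter and a stricter one, every probe tested, array weights, a trended and robust variance prior, each time normalized and fitted alone, a replicate block and omission of each array.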

Results

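Gene expression was measured in the triceps surae, the calf muscle group, of 4-month-old C57/Bl6 mice on Illumina beadchips. Wild-type mice and mice lacking MuRF1, the muscle ubiquitin ligase encoded by Trim63, either received dexamethasone, a synthetic glucocorticoid, at 3 mg/kg in the drinking water or were left untreated. Muscles were taken after 3 or 14 days, and each time had untreated littermate controls of its own. The 8 groups held 3 arrays each, 24 in all. Median probe signals ran from 81.0 to 101.9 per array and mean signals from 174.4 to 301.9, and between 29.0% and 36.1% of probes were detected. Arrays of one group correlated at r = 0.951 or more across probes, with a median of 0.987. The first principal component held 28.3% of the variance and the second 16.7%. On the first, knockout 3-day dexamethasone replicate 3 stood apart at 70.01, with all other arrays between -31.65 and 23.52. On the second, treated arrays lay between 10.35 and 22.61 and untreated arrays between -20.42 and -8.60. The number of arrays limits the precision of every comparison. Genes picked for the size of their change in the dexamethasone and genotype comparisons had all 3 arrays of one group on one side of the 3 arrays of the other, which chance gives in 10% of genes.

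Trim63, read by the single probe ILMN_3161061, was measured first because its level checks the genotype labels. Its log2 signal was 8.48 ± 0.102 in untreated wild-type muscle of the 3-day arm and 8.04 ± 0.0185 in that of the 14-day arm (SD, n = 3 each). Dexamethasone brought it to 9.59 ± 0.32 at 3 days and 9.67 ± 0.378 at 14 days, log2 fold changes of 1.10 (SE 0.187, adjusted p = 0.000566) and 1.63 (SE 0.187, adjusted p = 5.97e-06). In the knockout the signal was 4.64 ± 0.192 untreated and 4.75 ± 0.113 treated in the 3-day arm, and 4.87 ± 0.366 untreated and 4.64 ± 0.0695 treated in the 14-day arm. The probe was detected on 1 of 3 arrays in each 3-day knockout group, on 2 of 3 in the untreated and on 0 of 3 in the treated 14-day knockout, so knockout signals lay close to background. No label went against it: all 12 knockout arrays lay below all 12 wild-type arrays. In knockout muscle the log2 fold change under dexamethasone was 0.11 at 3 days (adjusted p = 0.803) and -0.23 at 14 days (adjusted p = 0.642), values that lie at background. Whether the probe lies in the deleted part of the gene is not given in the sources used here.

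**Figure D1:**
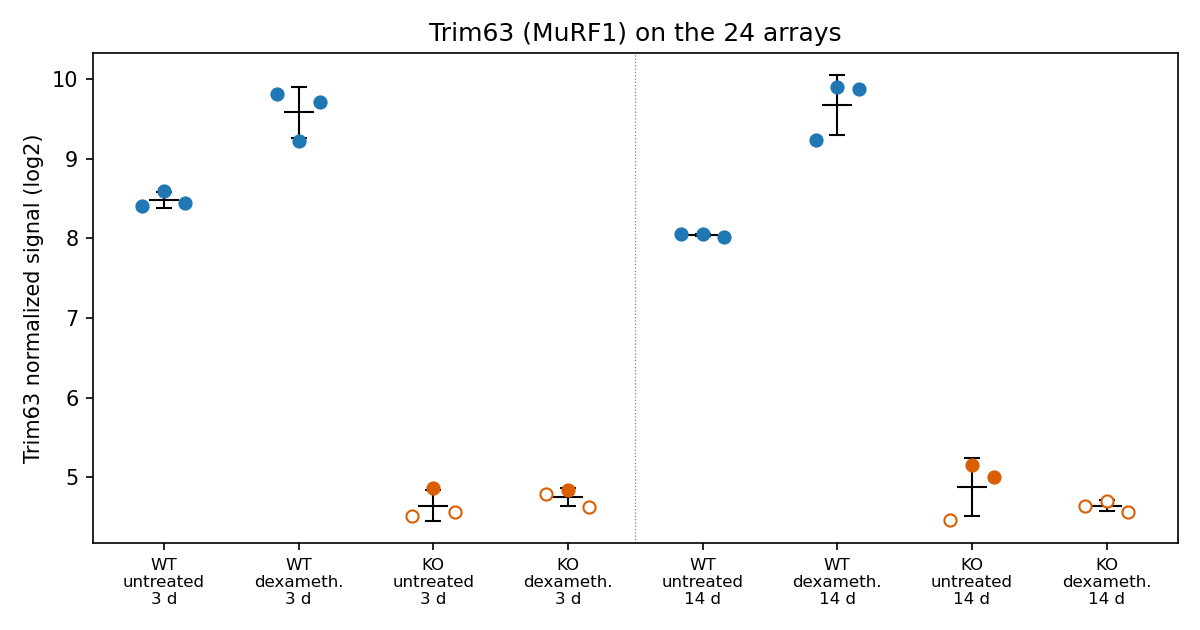
Normalized log2 signal of Trim63 on each of the 24 arrays by genotype, treatment and time (blue wild type, orange knockout; hollow points have a detection p of 0.05 or more; bars are mean ± SD of 3 arrays). Wild-type means lie between 8.04 and 9.67 and knockout means between 4.64 and 4.87.

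Short exposure in wild type was examined first among the drug comparisons. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 6.35 ± 0.105 to 9.50 ± 0.123 (SD, n = 3 each; log2 fold change 3.15, SE 0.225, adjusted p = 3.19e-09). Lcn2, an iron-siderophore-binding lipocalin, rose at least 8.58-fold (adjusted p = 3.96e-09), as it was not detected on any untreated array. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose by 2.80 on the log2 scale (SE 0.252), Tnfrsf12a, the TWEAK receptor, by 2.43 (SE 0.182) and Odf3l2 by 3.78 (SE 0.373). The deepest fall was that of Actc1, cardiac alpha-actin, from 11.9 ± 0.448 to 7.31 ± 0.225 (log2 fold change -4.64, SE 0.245, adjusted p = 1.98e-11). Dbp, a transcription factor of clock output, fell by 3.63 (SE 0.297). Col1a1, a chain of type I collagen, fell by 2.70 (SE 0.264). Further large increases were those of Hp at 2.36, Pde4d at 2.02, and Ppp1r3c, which targets protein phosphatase to glycogen, at 1.95 (log2 fold changes). Further decreases were those of Nrep at -3.16, Gamt at -2.56, Rsph1 at -2.39 and Igfbp5 at -2.28. In all, 634 of 16262 features passed, 320 higher and 314 lower. Of these, 91 of the higher and 89 of the lower differed by at least 2-fold.

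Gene lists described these changes by function. Of 29 measured glucocorticoid-responsive genes 11 rose, 0 fell and 18 did not pass, against 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.09e-18 and adjusted p = 0.0232 with an estimated correlation). Among 18 ubiquitin ligases and partners linked to atrophy 4 rose, including Fbxo32 (atrogin-1) at 1.53, Trim63 at 1.10 and Asb2 at 0.79, and 1 fell (5 higher and 1 lower adjusted over the list alone). That list had a camera adjusted p of 0.00674, and adjusted p = 0.272 with an estimated correlation. Proteasome subunits rose in 8 of 34 and fell in 0, among them Psmd8 at 1.28, Psmd2 at 1.09 and Psma7 at 0.77 (12 higher adjusted over the list alone, camera adjusted p = 3.77e-11 and adjusted p = 0.054 with an estimated correlation). Autophagy and lysosome genes rose in 4 of 28, among them Map1lc3a at 1.03, Gabarapl1 at 0.91 and Gaa, the lysosomal glucosidase, at 0.80 (6 higher adjusted over the list alone, camera adjusted p = 0.00873 and adjusted p = 0.343 with an estimated correlation).

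Matrix and connective tissue lists were shifted downward in the same muscles. Of 43 extracellular matrix genes 11 fell and 0 rose, with Lum at -1.58, Col1a2 at -1.57 and Col6a1 at -1.40 beside Col1a1 (13 lower and 1 higher adjusted over the list alone, camera adjusted p = 2e-08 and adjusted p = 0.115 with an estimated correlation). Fibroblast markers fell in 7 of 16, including Thy1 at -1.54 and Col15a1 at -1.28 (8 lower adjusted over the list alone, camera adjusted p = 3.77e-11 and adjusted p = 0.0513 with an estimated correlation). Tendon markers fell in 3 of 10, with Cilp2 at -2.07 and Kera at -1.54 (7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000131 and adjusted p = 0.132 with an estimated correlation). Interferon and antigen presentation genes fell in 7 of 26, with the class II genes H2-Ab1 at -1.61 and Cd74 at -1.12 (11 lower adjusted over the list alone, camera adjusted p = 2.07e-08 and adjusted p = 0.0485 with an estimated correlation). Macrophage markers fell in 5 of 18, with Mrc1 at -0.97 (6 lower adjusted over the list alone, camera adjusted p = 0.000129 and adjusted p = 0.243 with an estimated correlation). Red blood cell markers fell in 4 of 7, namely Hbb-bs at -2.33, Hbb-bt at -2.26, Hba-a1 at -2.18 and Alas2, the erythroid enzyme of haem synthesis, at -1.55 (4 lower adjusted over the list alone, camera adjusted p = 1.14e-09 and adjusted p = 0.00465 with an estimated correlation). Hbb-bs and Hbb-bt are near-identical copies, so their probes are not separate measurements.

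Clock and metabolic lists also moved at 3 days. Of 14 clock genes 6 fell and 1 rose, with Ciart at -1.57 and Per3 at -1.24 beside Dbp (8 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.000131 and adjusted p = 0.0454 with an estimated correlation). Fatty acid oxidation and lipid genes rose in 3 of 29 and fell in 1, with Pdk4, which inhibits pyruvate dehydrogenase, at 1.73, the lipase Pnpla2 at 1.22 and Ppargc1b at -0.98 (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000937 and adjusted p = 0.243 with an estimated correlation). The heat shock list was shifted upward with 2 of 23 members past the threshold, among them Hsph1 at 1.04 (4 higher adjusted over the list alone, camera adjusted p = 0.0287 and adjusted p = 0.357 with an estimated correlation). Slow fibre genes were shifted upward with 1 of 14 past the threshold, Myoz2, whose call was lost under 6 of 18 alternatives (1 higher adjusted over the list alone, camera adjusted p = 0.00873 and adjusted p = 0.504 with an estimated correlation). Downward shifts were called for oxidative phosphorylation, with 0 of 55 members past the threshold in limma and 0 adjusted over the list alone (camera adjusted p = 0.00706 and adjusted p = 0.504 with an estimated correlation). They were also called for glycolysis, where Ppp1r3c was the 1 member of 21 to pass and rose (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0262 and adjusted p = 0.504 with an estimated correlation). Calcium handling was shifted downward with 2 of 25 higher and 2 lower, among them Mss51 at 1.71 and Casq1, calsequestrin of fast fibres, at -1.33 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.027 and adjusted p = 0.504 with an estimated correlation). The count of 634 fell to 418 without untreated wild-type 3-day replicate 2. It fell to 398, 403 and 393 without wild-type 3-day dexamethasone replicates 1, 2 and 3.

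**Figure D2:**
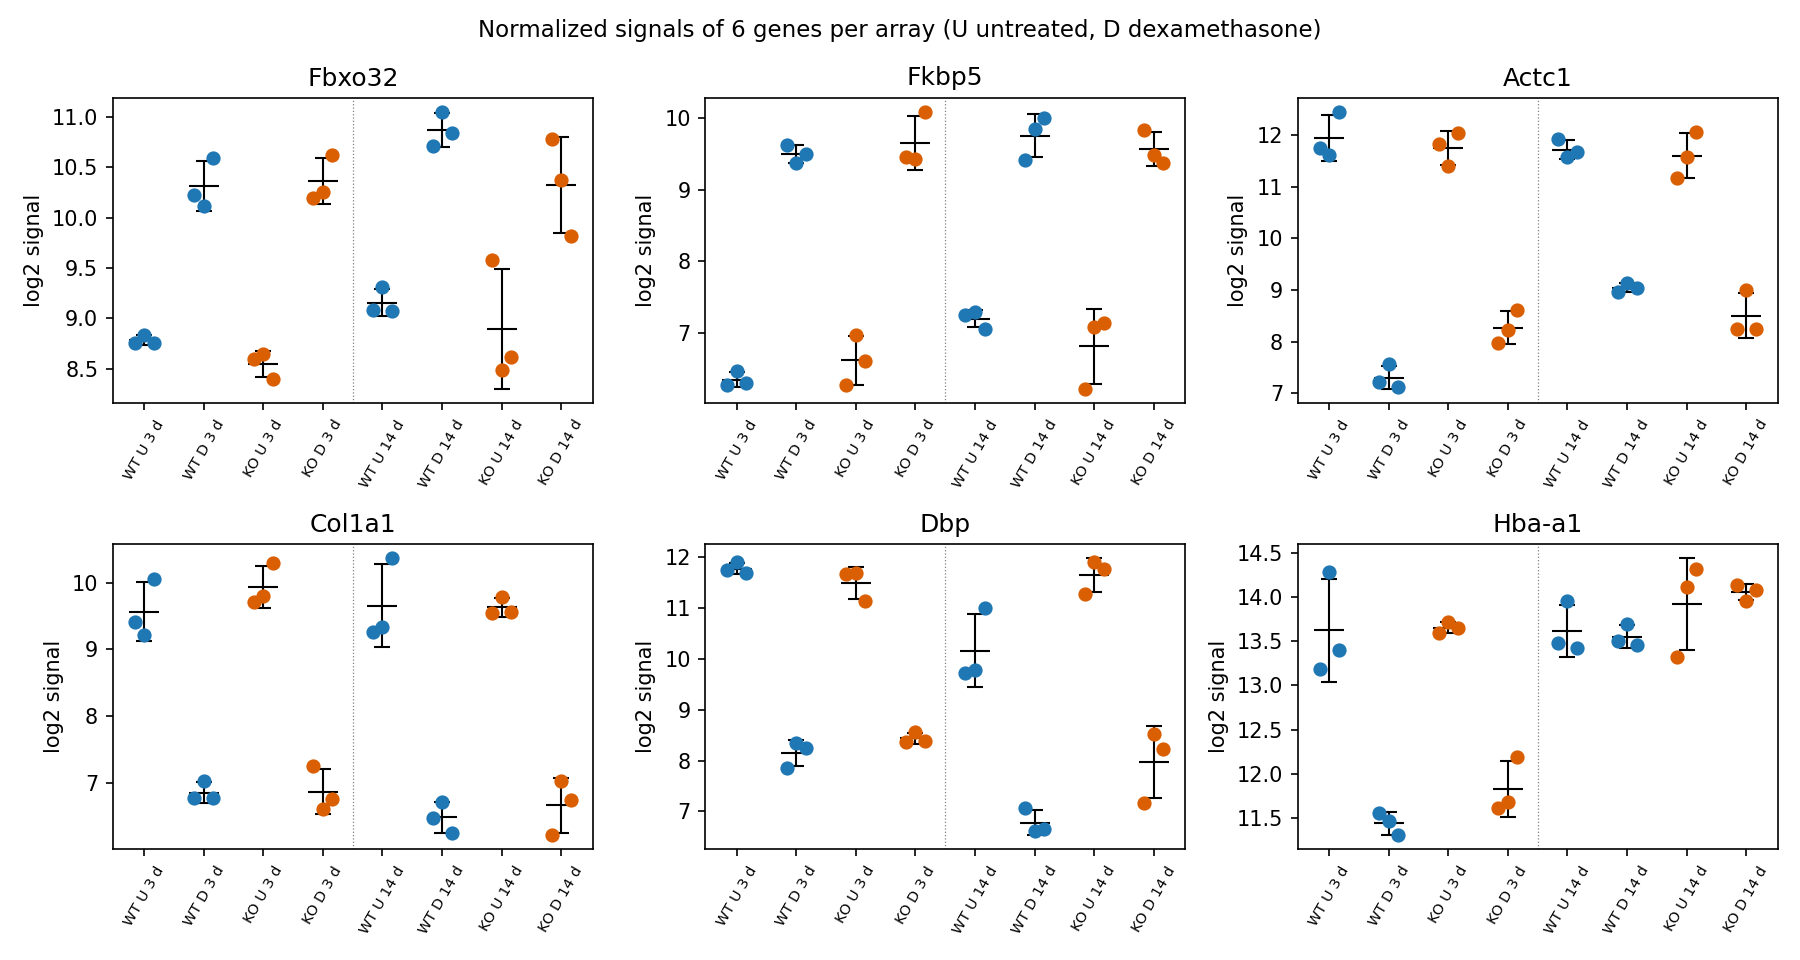
Normalized log2 signals of Fbxo32, Fkbp5, Actc1, Col1a1, Dbp and Hba-a1 on each array (blue wild type, orange knockout; U untreated, D dexamethasone; bars are mean ± SD of 3 arrays). Hba-a1 lies lower in treated muscle in the 3-day arm, with log2 fold changes of -2.18 in wild type and -1.82 in the knockout.

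After 14 days of treatment in wild type, Odf3l2 was higher by 3.99 on the log2 scale (SE 0.373, adjusted p = 2.71e-07) and Gsta3, a glutathione transferase, was 9.16-fold higher (adjusted p = 7.87e-07). Fkbp5 rose from 7.20 ± 0.123 to 9.76 ± 0.304 (SD, n = 3 each; log2 fold change 2.56, SE 0.225, adjusted p = 1.15e-07). Cxcl13, a B-cell chemokine, rose by 2.64 (SE 0.218), Galnt15 by 2.80 (SE 0.198) and Cish, a suppressor of cytokine signalling, by 2.78 (SE 0.372). Dbp fell by 3.38 (SE 0.297) and Col1a1 fell from 9.66 ± 0.616 to 6.49 ± 0.232 (log2 fold change -3.17, SE 0.264, adjusted p = 7.61e-08). Cdkn1a at 2.87, Hp at 2.85, Klk1b26 at 2.43 and Arrdc2 at 2.42 rose as well, and Actc1 at -2.68, Nrep at -2.13 and Rsph1 at -2.12 fell. In all, 489 features passed, 201 higher and 288 lower, with 99 and 81 of them at least 2-fold apart.

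Glucocorticoid-responsive genes rose in 12 of 29 and fell in 0 at 14 days, including Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, at 2.36 (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.31e-25 and adjusted p = 0.00833 with an estimated correlation). Insulin, IGF and mTOR genes rose in 4 of 26 and fell in 2, with Igfbp3 at 2.11 and Foxo1 at 1.54 (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00561 and adjusted p = 0.0199 with an estimated correlation). Extracellular matrix genes fell in 17 of 43 and rose in 0, with Col15a1 at -2.15, Col1a2 at least 3.01-fold lower and Col3a1 at least 2.49-fold lower (24 lower adjusted over the list alone, camera adjusted p = 5.12e-24 and adjusted p = 0.00833 with an estimated correlation). Fibroblast markers fell in 9 of 16, with Thy1 at -2.15 and Lum at -1.20 (11 lower adjusted over the list alone, camera adjusted p = 5.76e-17 and adjusted p = 0.0186 with an estimated correlation). Tendon markers fell in 4 of 10, with Cilp2 at -2.69 and Tnmd, tenomodulin, at -1.71 (6 lower adjusted over the list alone, camera adjusted p = 9.81e-07 and adjusted p = 0.05 with an estimated correlation). Of 26 interferon and antigen presentation genes 5 fell, with Cd74 at -1.92, H2-Ab1 at -1.88 and H2-Aa at -1.61 (10 lower adjusted over the list alone, camera adjusted p = 7.33e-10 and adjusted p = 0.0199 with an estimated correlation). Macrophage markers fell in 4 of 18, with Laptm5 at -0.80 (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0164 and adjusted p = 0.538 with an estimated correlation).

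Adipocyte markers rose in 3 of 14 and fell in 1 at this time, with Cidec, a lipid droplet protein, at 1.83 (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.4e-05 and adjusted p = 0.241 with an estimated correlation). Lipid genes rose in 4 of 29, with Angptl4 at 1.87 and Pdk4 at 1.49 (7 higher adjusted over the list alone, camera adjusted p = 0.000521 and adjusted p = 0.241 with an estimated correlation). Amino acid genes rose in 2 of 31, glutamine synthetase Glul at 2.07 and proline dehydrogenase Prodh at 1.10 (4 higher adjusted over the list alone, camera adjusted p = 0.0472 and adjusted p = 0.538 with an estimated correlation). Myostatin and BMP signalling genes fell in 2 of 25, Fstl1 at -1.73 and Bmp1 at -0.79 (7 lower adjusted over the list alone, camera adjusted p = 0.0124 and adjusted p = 0.387 with an estimated correlation). Calcium handling genes fell in 2 of 25, Sypl2 at -1.02 and Casq1 at -0.89 (3 lower adjusted over the list alone, camera adjusted p = 0.028 and adjusted p = 0.592 with an estimated correlation). Fbxo32 at 1.71 and Trim63 at 1.63 rose, but the ubiquitin ligase list was not called, with 3 higher and 1 lower of 18 (4 higher and 1 lower adjusted over the list alone). Its median was -0.02 and its test upward at camera adjusted p = 0.0972. Proteasome subunits had 0 of 34 past the threshold in limma and 0 adjusted over the list alone (camera adjusted p = 0.757). Clock genes had 3 of 14 lower (5 lower and 1 higher adjusted over the list alone), with Nr1d1 at -1.19 beside Dbp. The list median was 0.12 and the test downward at camera adjusted p = 0.0996. Untreated wild-type muscle itself differed between the arms in 6 of 14 clock genes, so the 3-day and 14-day clock responses have unlike baselines. The count of 489 fell to 249 without wild-type 14-day dexamethasone replicate 2.

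**Figure D3:**
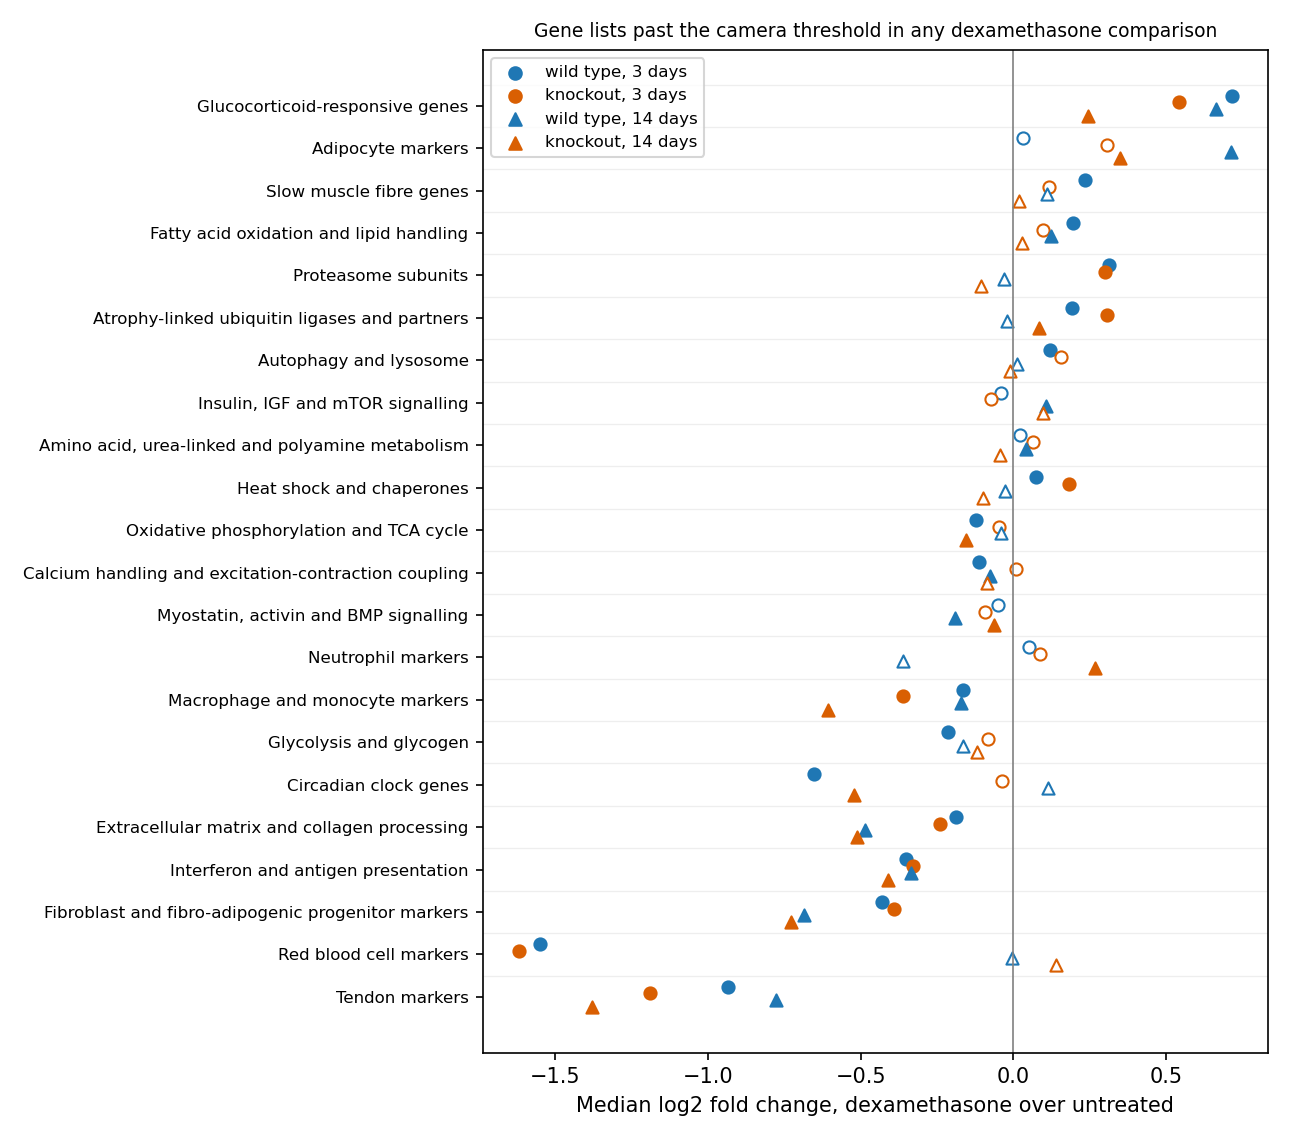
Median log2 fold change, dexamethasone over untreated, of each gene list called in a dexamethasone comparison (circles 3 days, triangles 14 days; blue wild type, orange knockout; filled symbols are past the camera threshold). Glucocorticoid-responsive genes had medians of 0.72 and 0.66 in wild type at 3 and 14 days, and red blood cell markers -1.55 and -0.01.

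The same 3-day treatment was then read in knockout muscle. Tnfrsf12a rose from 7.52 ± 0.197 to 10.9 ± 0.0693 (SD, n = 3 each; log2 fold change 3.35, SE 0.182, adjusted p = 3.59e-11), Cdkn1a by 3.17 (SE 0.252) and Fkbp5 by 3.04 (SE 0.225, adjusted p = 5.4e-09). Rgcc, a regulator of the cell cycle, rose by 2.33 (SE 0.163, adjusted p = 2.35e-09) and Eif4ebp1, a repressor of translation initiation, by 2.15. Actc1 fell by 3.48 (SE 0.245, adjusted p = 2.35e-09) and Ky, a muscle protease-like protein, differed by -2.49 (SE 0.416, adjusted p = 0.000496). Dbp and Col1a1 changed by -3.06 each. Lcn2 was at least 5.53-fold higher, Hectd2 rose by 2.30 on 1 of its 4 kept probes, with the others between -0.22 and 0.05, and Nrep at -2.88, Ecrg4 at -2.71 and Rsph1 at -2.53 fell. In all, 880 features passed, 469 higher and 411 lower, with 94 and 147 of them at least 2-fold apart.

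In this comparison 9 of 29 glucocorticoid-responsive genes rose and 1 fell (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.2e-09 and adjusted p = 0.121 with an estimated correlation). Ubiquitin ligases and partners rose in 4 of 18, with Fbxo32 at 1.81 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000229 and adjusted p = 0.121 with an estimated correlation). Proteasome subunits rose in 7 of 34, with Psmd8 at 1.53, Psmd4 at 0.87 and Psma7 at 0.71 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.29e-08 and adjusted p = 0.121 with an estimated correlation). Heat shock genes rose in 6 of 23, with Hspb7 at 1.03, Hsph1 at 0.95 and Hspb1 at 0.82 (8 higher adjusted over the list alone, camera adjusted p = 0.000229 and adjusted p = 0.121 with an estimated correlation). Extracellular matrix genes fell in 12 of 43, with Lum at -1.53 and Col6a1 at -1.29 (12 lower adjusted over the list alone, camera adjusted p = 5.29e-08 and adjusted p = 0.121 with an estimated correlation). Fibroblast markers fell in 6 of 16, with Thy1 at -1.45 and Smoc2 at -1.02 (7 lower adjusted over the list alone, camera adjusted p = 1.99e-07 and adjusted p = 0.121 with an estimated correlation). Tendon markers fell in 6 of 10, with Cilp2 at -2.45, Kera at -1.93 and Comp at -1.73 (7 lower adjusted over the list alone, camera adjusted p = 1.02e-06 and adjusted p = 0.121 with an estimated correlation). Interferon and antigen presentation genes fell in 7 of 26, with H2-Ab1 at -1.41 and Cd74 at -1.30 (9 lower adjusted over the list alone, camera adjusted p = 5.12e-06 and adjusted p = 0.121 with an estimated correlation). Macrophage markers fell in 4 of 18, with Mrc1 at -0.77, a call lost under 2 of 18 alternatives (8 lower adjusted over the list alone, camera adjusted p = 0.000615 and adjusted p = 0.343 with an estimated correlation). Red blood cell markers fell in 4 of 7, with Hbb-bt at -2.68, Hbb-bs at -2.56 and Alas2 at -1.62 (5 lower adjusted over the list alone, camera adjusted p = 1.25e-07 and adjusted p = 0.0155 with an estimated correlation). The count of 880 was 495 without untreated knockout 3-day replicate 3. It was 1338 without knockout 3-day dexamethasone replicate 1 and 521 without its replicate 3, the array that correlated least with its group.

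At 14 days in the knockout, Dbp fell from 11.6 ± 0.33 to 7.97 ± 0.704 (SD, n = 3 each; log2 fold change -3.68, SE 0.297, adjusted p = 5.22e-08). H2-Ab1, a class II antigen-presenting chain, changed by -2.57 (SE 0.23, adjusted p = 1.47e-07). Actc1 changed by -3.10, Col1a1 by -2.96 and Per2, a core clock repressor, by -2.29. Odf3l2 rose by 3.11 (SE 0.373, adjusted p = 8.69e-06), Cdkn1a by 2.96 and Fkbp5 by 2.75 (SE 0.225, adjusted p = 5.23e-08). Gsta3 at 2.49, Hectd2 at 2.51 (other probes between -0.31 and 0.14), Ttll7 at 2.23, Lcn2 at 2.30 and Cxcl13 at 2.20 were also higher, and Rsph1 at -2.58 and Ecrg4 at -2.20 lower. In all, 535 features passed, 183 higher and 352 lower, with 81 and 93 of them at least 2-fold apart.

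Among the lists, 8 of 29 glucocorticoid-responsive genes rose and 1 fell in the 14-day knockout (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.7e-09 and adjusted p = 0.0979 with an estimated correlation). Extracellular matrix genes fell in 18 of 43, with Col1a2 at -1.66, Ccn2, a matricellular growth factor, at -1.62 and Fn1 at -1.54 (28 lower adjusted over the list alone, camera adjusted p = 7.77e-23 and adjusted p = 0.015 with an estimated correlation). Fibroblast markers fell in 8 of 16, with Thy1 at -1.81 and Lum at -1.22 (15 lower adjusted over the list alone, camera adjusted p = 2.45e-18 and adjusted p = 0.015 with an estimated correlation). Tendon markers fell in 7 of 10, with Cilp2 at -2.56, Chad at -2.17 and Kera at -2.15 (7 lower adjusted over the list alone, camera adjusted p = 1.09e-09 and adjusted p = 0.0156 with an estimated correlation). Interferon and antigen presentation genes fell in 7 of 26, with Cd74 at -2.41, H2-Eb1 at -2.35 and H2-Aa at -2.06 (12 lower adjusted over the list alone, camera adjusted p = 3.33e-11 and adjusted p = 0.015 with an estimated correlation). Macrophage markers fell in 4 of 18, with Laptm5 at -1.08, C1qa at -0.84 and Adgre1 at -0.69 (11 lower adjusted over the list alone, camera adjusted p = 1.09e-09 and adjusted p = 0.0524 with an estimated correlation). Clock genes fell in 6 of 14 and rose in 1 (7 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.84e-05 and adjusted p = 0.015 with an estimated correlation).

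Smaller list shifts were called in the same comparison. The ubiquitin ligase list was shifted upward with Fbxo32 at 1.43 the 1 member of 18 to pass (3 higher adjusted over the list alone, camera adjusted p = 0.0429 and adjusted p = 0.518 with an estimated correlation). Adipocyte markers were shifted upward with 1 of 14 higher and 1 lower (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.025 and adjusted p = 0.536 with an estimated correlation). Neutrophil markers were shifted upward with Lcn2 the 1 of 6 to pass (1 higher adjusted over the list alone, camera adjusted p = 0.0293 and adjusted p = 0.323 with an estimated correlation). Myostatin and BMP signalling genes fell in 2 of 25, Fstl1 at -1.74 and Bmp1 at -0.95 (6 lower adjusted over the list alone, camera adjusted p = 0.013 and adjusted p = 0.397 with an estimated correlation). Oxidative phosphorylation genes were shifted downward with 0 of 55 past the threshold in limma and 0 adjusted over the list alone (camera adjusted p = 0.013 and adjusted p = 0.571 with an estimated correlation). The count of 535 was 813, 298 and 296 without untreated knockout 14-day replicates 1, 2 and 3. It was 307 and 317 without knockout 14-day dexamethasone replicates 1 and 2.

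Wild type and knockout shared much of their response to dexamethasone. At 3 days 200 features were higher in both genotypes where independent lists would share 9.23. A further 195 were lower in both against 7.94, and 0 went in opposite directions. At 14 days 90 were higher in both against 2.26, 145 were lower in both against 6.23, and again 0 were opposite. The genotypes share no arrays. Fold changes of the genotypes correlated across genes at r = 0.642 at 3 days and r = 0.594 at 14 days, and genes are not independent replicates. Whether the response differed by genotype was tested as an interaction. At 3 days 0 features passed in limma (smallest adjusted p = 0.0956; Trim63 at -0.997, adjusted p = 0.996), with 710 at an unadjusted p under 0.05, and 1 passed without knockout 3-day dexamethasone replicate 1. At 14 days 2 passed and both were lower, Trim63 at -1.86 (SE 0.264, adjusted p = 0.00522; its knockout signals lay near background) and the unnamed probe ILMN_2466718 at -1.65. At this time 791 features were at an unadjusted p under 0.05. Neither 710 nor 791 exceeds what a cutoff of 0.05 gives among 16262 features with no interaction at all. The count of 2 past the threshold was 1 without untreated wild-type replicate 1, wild-type dexamethasone replicate 1 or 3, untreated knockout replicate 2 or 3, or knockout dexamethasone replicate 1 or 3 of the 14-day arm, and 3 without untreated wild-type replicate 3. On the authors' value table it was 1 higher and 5 lower.

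For gene lists the 14-day interaction between genotype and dexamethasone was called downward for 4 lists and upward for 1, and for 0 with an estimated correlation. Glucocorticoid-responsive genes had the smallest p (median -0.27, 0 of 29 past the threshold in limma and 0 adjusted over the list alone, camera adjusted p = 0.000126 and adjusted p = 0.627 with an estimated correlation). Macrophage markers were shifted downward (median -0.38, 0 of 18 past the threshold in limma and 0 adjusted over the list alone, camera adjusted p = 0.000637 and adjusted p = 0.627 with an estimated correlation). Neutrophil markers were shifted upward (median 0.43, 0 of 6 past the threshold in limma and 1 higher adjusted over the list alone, camera adjusted p = 0.0104 and adjusted p = 0.608 with an estimated correlation). Downward shifts were also called for amino acid genes (median -0.08, 0 of 31 past the threshold in limma and 0 adjusted over the list alone, camera adjusted p = 0.0146 and adjusted p = 0.703 with an estimated correlation). Clock genes completed the set (median -0.25, 0 of 14 past the threshold in limma, 1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0323 and adjusted p = 0.608 with an estimated correlation). Between the untreated arms 6 of 14 clock genes differed in wild type and 0 in the knockout, so the shift of clock genes may lie in the untreated wild-type arrays. Macrophage and neutrophil markers were called between untreated genotypes of the 14-day arm, each opposite in direction to its interaction. Neither list was called between genotypes under 14-day treatment, so these shifts may lie in the untreated arrays as well.

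**Figure D4:**
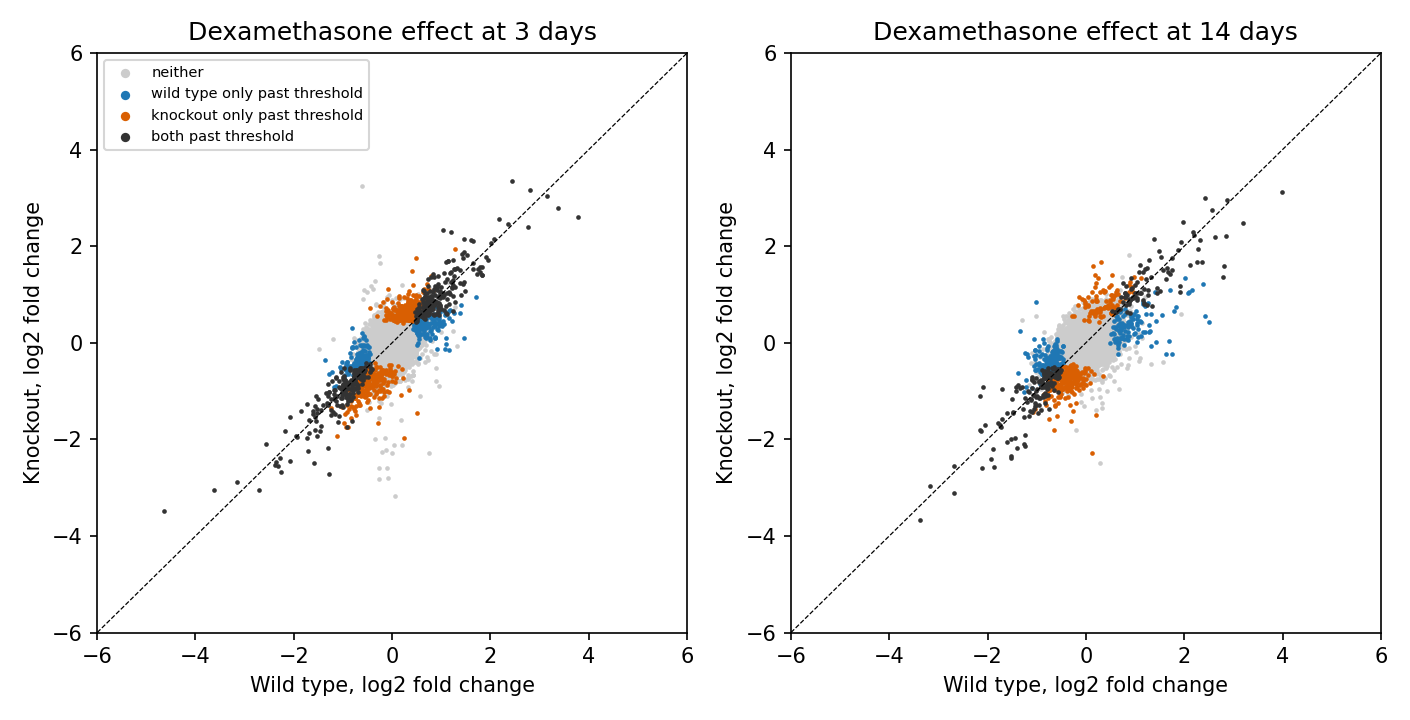
Log2 fold change under dexamethasone of each feature in wild type (horizontal) and knockout (vertical) at 3 and 14 days, coloured by which genotype passed the threshold; the dashed line marks equal change. Across genes r was 0.642 at 3 days and 0.594 at 14 days.

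Responses at 14 days were then set against those at 3 days within each genotype. In wild type the fall of the globin genes at 3 days was not seen at 14 days, so their difference between times was positive. It was 2.39 for Hbb-bt (SE 0.387, adjusted p = 0.00605) and 2.11 for Hba-a1 (SE 0.339, adjusted p = 0.00605). Hbb-bt had changed by -2.26 at 3 days. At 14 days log2 signals of Hba-a1 ran from 13.42 to 13.95 untreated and from 13.45 to 13.70 treated. Tnfrsf12a at -1.83 (SE 0.258, adjusted p = 0.0023), Ppp1r27 at -1.72 (SE 0.216, adjusted p = 0.000708) and Ripply3 at -1.19 had a lower 14-day response, and Stc2, a secreted glycoprotein hormone, differed by 1.80. In the knockout Hbb-bs differed by 2.91 (SE 0.394, adjusted p = 0.000831), Hbb-bt by 2.88, Tnfrsf12a by -2.29 (SE 0.258, adjusted p = 9.57e-05) and Mustn1 by -1.22. Trim63 did not pass, at 0.53 in wild type (adjusted p = 0.669) and -0.34 in the knockout (adjusted p = 0.555). Wild type had 24 features past the threshold, 10 higher and 14 lower, and the knockout 21, 11 higher and 10 lower. The knockout split was 15 and 47 without background correction, 10 and 3 with arrays scaled on their 75th percentile and 11 and 21 on the authors' value table. The wild-type count of 24 was 14 without untreated 3-day replicate 1 or 2. It was 12 and 10 without 3-day dexamethasone replicates 2 and 3, and 15 and 14 without 14-day dexamethasone replicates 1 and 2. The knockout count of 21 was 5 without untreated 3-day replicate 3 and 116 without 3-day dexamethasone replicate 1. It was 366, 10 and 8 without untreated 14-day replicates 1, 2 and 3, and 9 without 14-day dexamethasone replicate 2.

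Lists moved between times as well, 10 of them called in wild type and 4 in the knockout, and 1 in each with an estimated correlation. Red blood cell markers, which had fallen at 3 days, had a positive difference in 3 of 7 in each genotype (4 higher in each adjusted over the list alone, camera adjusted p = 2.77e-08 and 2.67e-06 and adjusted p = 0.00863 and 0.0306 with an estimated correlation). Proteasome subunits were shifted downward with medians of -0.38 and -0.47 and 0 of 34 past the threshold in limma (10 and 16 lower adjusted over the list alone, camera adjusted p = 2.49e-10 and 1.21e-09 and adjusted p = 0.119 and 0.218 with an estimated correlation). Heat shock genes were shifted downward in both, with medians of -0.17 and -0.43 and 1 of 23 and 0 lower past the threshold in limma (1 and 4 lower adjusted over the list alone, camera adjusted p = 0.00749 and 0.00023 and adjusted p = 0.323 and 0.251 with an estimated correlation). Adipocyte markers were shifted upward in wild type with a median of 0.69 and 0 of 14 past the threshold in limma (3 higher adjusted over the list alone, camera adjusted p = 1.77e-06 and adjusted p = 0.258 with an estimated correlation). Extracellular matrix genes were shifted downward in both genotypes with 0 of 43 past the threshold in limma (1 and 0 lower adjusted over the list alone, camera adjusted p = 6.14e-05 and 0.0107 and adjusted p = 0.323 and 0.814 with an estimated correlation). Insulin, IGF and mTOR genes were called upward in wild type and not called in the knockout (median 0.20 in wild type, camera adjusted p = 0.0279 and adjusted p = 0.119 with an estimated correlation). Autophagy genes (median -0.22, camera adjusted p = 0.013), neutrophil markers (median -0.57, camera adjusted p = 0.00871), inflammatory genes (median -0.40, camera adjusted p = 0.0312) and satellite cell markers (median -0.34, camera adjusted p = 0.0312) were called downward in wild type and not called in the knockout. For these 4 lists it was adjusted p = 0.445, 0.272, 0.445 and 0.323 with an estimated correlation. Whether the shift between times of any list differed between genotypes was not tested.

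Genotypes were also compared directly within each treatment and time. Trim63 differed by -3.84 in untreated muscle of the 3-day arm (SE 0.187, adjusted p = 1.56e-12). Hspb7, a small heat shock protein of striated muscle, was lower in untreated knockout muscle of the 3-day arm by a log2 difference of -3.80 (SE 0.228, adjusted p = 6.04e-11; 5.91 ± 0.175 against 9.72 ± 0.373, SD, n = 3 each). Pnrc2, a nuclear receptor coactivator, differed by -3.17, Xirp2, an actin-binding protein of muscle, by -2.66 (SE 0.25, adjusted p = 2.96e-07), Necap2, of clathrin-mediated endocytosis, by -2.05 and Bsdc1 by -1.67. Higher in the knockout were Hyi at 2.08 (SE 0.217, adjusted p = 1.73e-06), Haus1 at 1.71, Paip1, a regulator of translation, at 1.70 (SE 0.151, adjusted p = 1.29e-07), Rbp7, a retinol-binding protein, at 1.34 and Cap1 at 1.30. In all 53 features passed, 17 higher and 36 lower, or 18 and 78 with arrays scaled on their 75th percentile, and camera called 0 of 32 lists. Xirp2, Hyi and Rbp7 each have another, dimmer probe that did not pass, at -0.22, 0.19 and 0.59.

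Untreated knockout muscle of the 14-day arm again had lower Hspb7 at -3.76 (SE 0.228, adjusted p = 7.71e-11), Pnrc2 at -3.35, Xirp2 at -3.21, Trim63 at -3.17 and Necap2 at -2.41. Higher were Hyi at 2.37, Paip1 at 1.73, Itgb3bp at 1.52, Erdr1 at 4.10 (SE 0.703, adjusted p = 0.0029) and the clock gene Per2 at 2.28 (SE 0.388, adjusted p = 0.00283), and Rbp7 was at least 2.51-fold higher. In all 57 features passed, 23 higher and 34 lower, or 30 and 29 without background correction and 1396 and 1290 with array weights. The count was 163 without untreated knockout replicate 1 and 35 without its replicate 3. Clock genes were higher in 3 of 14, Per2, Dbp, a call lost under 7 of 18 alternatives, and Ciart at 1.24 (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0211 and adjusted p = 0.44 with an estimated correlation). Of 32 lists 4 were called in this comparison, and 0 with an estimated correlation. Macrophage markers were shifted upward (median 0.24, 0 of 18 past the threshold in limma and 3 higher adjusted over the list alone, camera adjusted p = 0.00457 and adjusted p = 0.772 with an estimated correlation). Neutrophil markers were shifted downward (median -0.43, 0 of 6 past the threshold in limma and 3 lower adjusted over the list alone, camera adjusted p = 0.00382 and adjusted p = 0.44 with an estimated correlation). Also called was the list of oxidative phosphorylation, shifted upward (median 0.17, camera adjusted p = 0.00171 and adjusted p = 0.772 with an estimated correlation). The same 3 clock genes had a median difference of -0.28 in the 3-day arm.

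Under dexamethasone for 3 days, knockout differed from wild type in Trim63 at -4.84 (SE 0.187, adjusted p = 8.94e-15), Hspb7 at -3.75, Pnrc2 at -3.66, Xirp2 at -2.87 and Necap2 at -2.21, with Rab6b at least 2.27-fold lower. Hyi at 2.79, Paip1 at 1.82, Slc30a2, a zinc transporter, at 1.81 (SE 0.243, adjusted p = 0.000123), Cap1 at 1.42 and Rgcc at 1.38 were higher. Slc30a2 lies next to Trim63 in gene order. In all 84 features passed, 36 higher and 48 lower, or 86 and 372 with arrays scaled on their 75th percentile and 886 and 821 with array weights. Camera called 0 of 32 lists. The count was 43 and 40 without wild-type dexamethasone replicates 1 and 2. Under dexamethasone for 14 days Trim63 was at least 30.7-fold lower (adjusted p = 3.65e-15), Hspb7 differed by -3.72 and Pnrc2 by -3.36. Lor, loricrin of the epidermal cornified envelope, differed by -5.24 (SE 0.985, adjusted p = 0.00881), a call lost under 4 of 18 alternatives. Slc30a2 at 2.19, Hyi at 2.00 and Paip1 at 1.61 were higher, and Rbp7 was at least 2.79-fold higher. In all 97 features passed, 42 higher and 55 lower, or 79 and 54 without background correction and 68 and 50 on the authors' value table. That count was 60 and 46 without wild-type dexamethasone replicates 1 and 2, and 52 and 46 without knockout dexamethasone replicates 1 and 2. Glucocorticoid-responsive genes were lower in 2 of 29 at 14 days (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.000386 and adjusted p = 0.974 with an estimated correlation). Insulin, IGF and mTOR genes were lower in 2 of 26 (3 lower adjusted over the list alone, camera adjusted p = 0.031 and adjusted p = 0.102 with an estimated correlation), with Igfbp3 at -1.53, a call lost under 1 of 18 alternatives. Adipocyte markers were shifted downward (median -0.51, 0 of 14 past the threshold in limma and 1 lower adjusted over the list alone, camera adjusted p = 0.0326 and adjusted p = 0.974 with an estimated correlation).

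Genes called between genotypes lay close to Trim63 in gene order more often than elsewhere. In untreated muscle of the 3-day arm 8 of 180 tested genes within 300 genes of Trim63 passed, or 4.44%. This compares with 8 of 467 farther away on the chromosome of Trim63, or 1.71%, and 22 of 10344 on other chromosomes, or 0.213%. All 8 were lower in the knockout, and Hspb7, Pnrc2, Necap2 and Bsdc1 were among them. In the untreated 14-day arm 9 of the 180 passed, all lower, or 5%, against 0.242% on other chromosomes. Under dexamethasone 9 were lower and 2 higher, Slc30a2 and Ahdc1, at 3 days (6.11% against 0.416%), and 9 lower and 1 higher, Slc30a2, at 14 days (5.56% against 0.474%). Features called in all 4 genotype comparisons numbered 28, of which 19 were lower and 9 higher in the knockout, and of the 21 named ones, Trim63 among them, 8 besides Trim63 lay within that window.

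**Figure D5:**
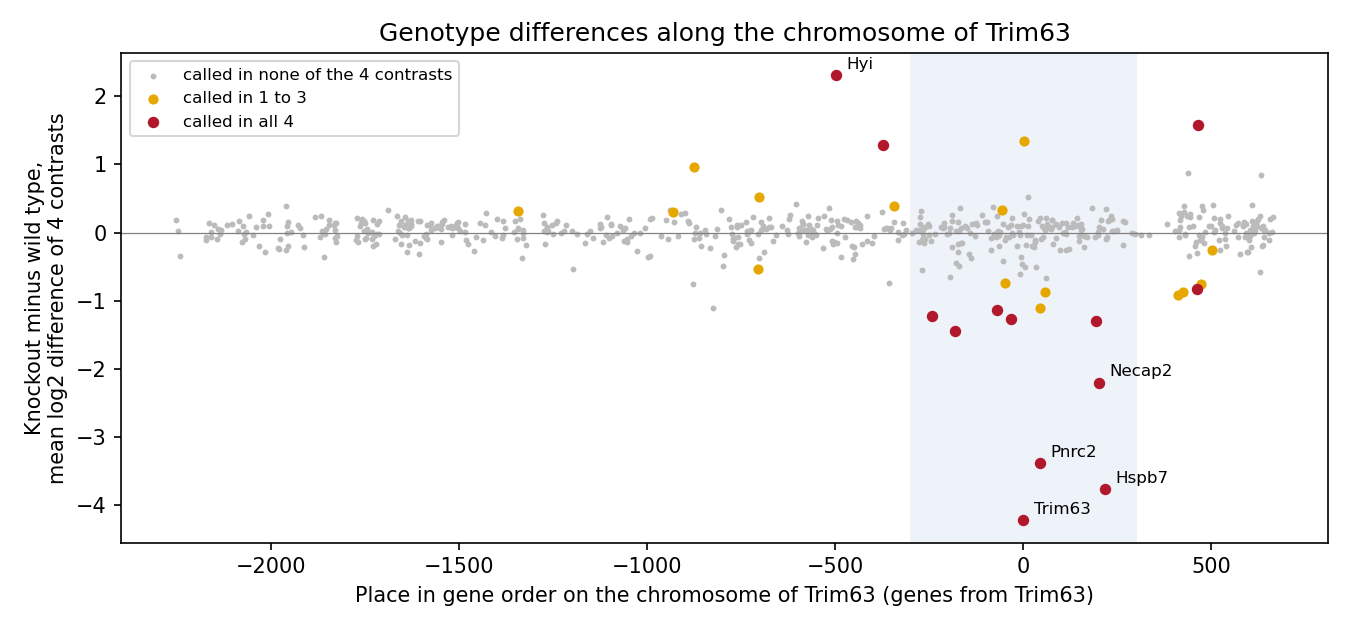
Knockout minus wild type, mean log2 difference over the 4 genotype comparisons, of tested genes by place in gene order along the chromosome of Trim63 (shaded, within 300 genes of Trim63; colours give the number of comparisons in which a gene passed). Hspb7, Pnrc2 and Necap2 lie in the shaded window, and Hyi outside it.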

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

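The tests of this part were planned, and none was chosen after the result was seen.

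Differences between groups in the response to dexamethasone drew attention to the results below, each from a test of the interaction itself. Between genotypes at 14 days 2 features passed, Trim63 at -1.86 and the unnamed probe ILMN_2466718 at -1.645 (log2 differences of fold changes, 3 arrays per group). The knockout removes Trim63, so its own difference restates the genotype. Of 100 splits of the same arrays, the real one among them, 14 gave at least as many features, and the highest gave 340 where genotypes were exchanged within one treatment. The splits exchanged genotypes separately within each treatment, so differences between the genotypes themselves enter the interaction. The share of 14 in 100 therefore cannot measure chance. At 3 days 0 features passed, so 100 of 100 splits, the real one among them, gave at least as many, which a count of 0 fixes in advance.

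Between times in wild type 24 features passed. The 14-day response lay above the 3-day response for Hbb-bt by 2.39, Hbb-bs by 2.32, Gsta3, a glutathione transferase, by 2.31, Hba-a1 by 2.11, Actc1 by 1.96 and Stc2 by 1.80 (log2). For the globins the fall at 3 days was not seen at 14 days. Actc1 fell at both times and changed less at 14 days, by -2.68 against -4.64 at 3 days. Over 23 alternatives the call of Gsta3 was lost under 13, that of Actc1 under 2 and that of Hbb-bs under 1. The response lay below for Tnfrsf12a by -1.83, Ppp1r27 by -1.72, Opn1mw by -1.40, Eln, the elastin gene, by -1.35, Hsph1, a chaperone, by -1.22 and Ripply3 by -1.19. Among these the call of Hsph1 was lost under 14 of 23 alternatives, that of Opn1mw under 11 and that of Eln under 1. Of 100 splits, the real one among them, 9 gave at least as many features, and the highest gave 1228 where times were exchanged. Differences between the arms themselves enter these splits, so the share of 9 in 100 cannot measure chance.

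Between times in the knockout 21 features passed. Higher were Hbb-bs at 2.91, Hbb-bt at 2.88, Hba-a1 at 1.96, Mybph, a myosin-binding protein, at 1.63, Aqp4, the water channel of fast fibres, at 1.36 and Ces1d at 0.99. Hbb-bs and Hbb-bt had changed by -2.56 and -2.68 at 3 days, falls that were not seen at 14 days. The call of Aqp4 was lost under 11 of 23 alternatives, that of Ces1d under 9, that of Mybph under 3 and that of Hba-a1 under 1. Lower were Tnfrsf12a at -2.29, Eif4ebp1 at -1.46, Rgcc at -1.22, Mustn1 at -1.22, Serf1 at -1.19 and Klhl30 at -1.08. The calls of Rgcc and Serf1 were lost under 11 of 23 alternatives each, that of Klhl30 under 7 and that of Eif4ebp1 under 2. Of 100 splits, the real one among them, 6 gave at least as many features, the highest being 1513 with 2 arrays moved. Counts from such splits depend on how single arrays are grouped and carry differences between the arms, so this share cannot measure chance either.

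For each of the 8 comparisons of 3 arrays with 3, the real grouping was the 1 of 10 splits to give as many features. The counts were 634 against a highest other of 0, 489 against 8, 880 against 0 and 535 against 1 for dexamethasone, and 53 against 0, 57 against 5, 84 against 0 and 97 against 0 for genotype. With 10 splits no share under 0.05 can be reached.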

How the results depend on the processing

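Most alternatives were planned, and the tests without the array standing apart and with the value table's replicate numbers were chosen after the results were seen.

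Of 422 named results past the threshold, 420 kept one direction and 291 also stayed past the threshold under all alternatives. Arrays scaled on their 75th percentile ended 61 of these calls, no detection filter 57, the value table of the authors ended 45, each time normalized and fitted alone 34 of 396, omission of the array standing apart 24, a trended and robust prior 23, no background correction 18, every probe tested 4, array weights 3 and stricter detection 0 of 421. Omission of single arrays, one at a time, ended the call in 453 of 2694 fits of these results and reversed it in 3. Correlations of fold changes between genotypes moved little, from 0.5498 to 0.6738 at 3 days and from 0.5108 to 0.6085 at 14 days with single arrays omitted. Of 51 list calls under dexamethasone 15 stayed with an estimated correlation, and 47 to 54 were made with single arrays omitted.

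Counts moved by more than 1.5 times as follows, and the cause was not tested unless given. Array weights gave 1662 and 2112 for dexamethasone at 3 days in wild type and knockout and 2873 in the knockout at 14 days. They gave 135, 2686, 1707 and 202 for genotype (untreated 3-day and 14-day arms, then treated), and 8, 47, 117 and 1072 for the interactions with genotype at 3 and 14 days and with time in wild type and knockout. Scaling on the 75th percentile gave 276 in wild type at 14 days, 575 in the knockout at 3 days, 96, 458 and 56 for genotype (untreated 3 days, treated 3 and 14 days), 1 for the 14-day interaction with genotype and 13 for the interaction with time in the knockout. The authors' value table gave 2 and 6 for the interactions with genotype and 32 for time in the knockout. No detection filter gave 1 and 1 for the interactions with genotype and 14 for time in wild type. The trended and robust prior gave 1 for the 3-day interaction with genotype and 35 for time in the knockout. No background correction gave 47 and 62 for time in wild type and knockout, and every probe tested gave 33 in the latter. Each time normalized and fitted alone gave 48 for genotype under 3-day treatment and 1 for the 14-day interaction. Without knockout 3-day dexamethasone replicate 3, the array standing apart, counts were 521 for dexamethasone in the knockout at 3 days and 162 for genotype under 14-day treatment.

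With single arrays omitted, counts ran from 393 to 465 and 249 to 406 for dexamethasone in wild type at 3 and 14 days, and from 495 to 1338 and 296 to 813 in the knockout. For genotype they ran from 37 to 48 and 35 to 163 untreated and from 40 to 92 and 46 to 121 treated. The interactions ran from 0 to 1 and 1 to 3 with genotype, and from 10 to 28 and 5 to 366 with time in wild type and knockout. Fewer arrays remained in each of these fits, and the cause of the higher counts was not tested.

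Of the named results 2 reversed, each because another probe of the gene became the brightest. Nmrk2 under 14-day treatment between genotypes went from 1.74 to -0.3209 with 75th percentile scaling, -0.4233 on the value table, -0.3917 without the array standing apart, and -0.3657 and -0.3809 without knockout replicates 2 and 3. Its range with single arrays omitted was -0.3809 to 1.802. Cblb in wild type at 14 days went from 0.74 to -0.02487 without untreated replicate 3, the lowest of a range up to 0.7862.

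Neither numbering of the replicates had every same-numbered pair above a correlation of 0.1, so neither was taken to pair the samples. By the numbers of the non-normalized table, deviations of same-numbered arrays correlated between -0.475 and 0.499 at 3 days and between -0.285 and 0.14 at 14 days, with 7 and 3 of 18 pairs above 0.1. By those of the value table, which differ in 5 of 8 groups, 11 of 18 pairs were above 0.1 at 3 days (median 0.226, against -0.161 for other pairs) and 5 of 18 at 14 days (median 0.0352). Deviations from a group mean cancel within the group, so the values of same-numbered and other pairs are not independent. The spread at 3 days may follow the value table's numbers, which the main fit without a block would ignore. Whether it does was not tested. A replicate block gave 565, 457, 773 and 477 for dexamethasone (wild type at 3 and 14 days, then knockout), 45, 55, 73 and 85 for genotype, 0 and 3 for the interactions with genotype and 18 and 14 with time, and ended 27 of the 422 named calls. With the value table's numbers the block gave 714, 537, 1095 and 594 for dexamethasone, 60, 64, 100 and 123 for genotype, 0 and 3 for the interactions with genotype and 18 and 54 with time, and ended 7 named calls. A block by BeadChip was not run, as no BeadChip is named. Signal over background limits what can be seen: between 29.0% and 36.1% of probes were detected per array, and changes are given as lower bounds only where no array of the lower group detected the probe.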

Other observations

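Tests of planned lists come first, and the tests of clock genes, of the share of calls near Trim63 and of keratinocyte markers were chosen after the results were seen.

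Several lists of cell and tissue compartments were called in none of the 4 dexamethasone comparisons. Schwann cell and nerve markers had 0 of 15 past the threshold in limma in all 4 comparisons (camera adjusted p = 0.267 and 0.423 in wild type at 3 and 14 days, 0.313 and 0.699 in the knockout). Endothelial markers had 0 of 18 at 3 days in both genotypes (camera adjusted p = 0.594 and 0.511), and 2 and 1 lower at 14 days in wild type and knockout (camera adjusted p = 0.286 and 0.0794). Fast fibre genes fell in 2 of 15 in wild type at 3 days, with Casq1 at -1.33, a list median of 0.01 and a downward test, and in 1 in each other comparison (camera adjusted p = 0.575 at 3 days and 0.336 at 14 days in wild type, 0.922 and 0.825 in the knockout). Neuromuscular junction genes rose in 3 of 20 in wild type at 3 days, with the acetylcholine receptor subunit Chrnb1 at 0.85, although the list median was -0.06 (camera adjusted p = 0.848). In the knockout at 3 days 2 of them rose and 1 fell (camera adjusted p = 0.864), and at 14 days 1 rose in each genotype (camera adjusted p = 0.726 in wild type and 0.847 in the knockout).

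Smooth muscle markers had 1 of 15 higher, Acta2 at 0.97, and 1 lower, Smtn at -0.91, in wild type at 3 days (camera adjusted p = 0.164), and 0 higher and 1 lower at 14 days (camera adjusted p = 0.892). In the knockout 2 were higher and 1 lower at 3 days (camera adjusted p = 0.313) and 1 higher and 1 lower at 14 days (camera adjusted p = 0.65). Satellite cell markers had 2 of 11 higher in each genotype at 3 days (camera adjusted p = 0.0576 in wild type and 0.345 in the knockout). At 14 days 1 was lower in wild type (camera adjusted p = 0.726), and 1 was higher and 3 lower in the knockout (camera adjusted p = 0.131). Lymphocyte markers had 0 of 8 past the threshold in limma in wild type at 3 days (camera adjusted p = 0.412, with a median of 0.04 and a downward test) and 2 lower in the knockout (camera adjusted p = 0.481). At 14 days 1 was lower in each genotype (camera adjusted p = 0.12 in wild type and 0.379 in the knockout).

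The oxidative stress, inflammatory and cell cycle lists were not called under dexamethasone either, with lowest camera adjusted p of 0.164, 0.0794 and 0.32. Oxidative stress genes rose in 4 of 25 and fell in 2 in wild type at 3 days, with the metallothioneins Mt1 at 2.77 and Mt2 at 1.11 and the peroxidase Gpx3 at 0.98 (camera adjusted p = 0.164). Inflammatory genes rose in 3 of 22 and fell in 1 there, with Cxcl13 at least 2.51-fold higher, Il6ra at 1.02 and Il15 at -1.19 (camera adjusted p = 0.425, median -0.03 with an upward test), and at 14 days rose in 2 and fell in 4 in wild type and rose in 3 and fell in 4 in the knockout. Cell cycle genes rose in 1 of 22, Cdkn1a, and fell in 2 in wild type at 3 days, among them the cyclin Ccnd1 at -1.29 (camera adjusted p = 0.32). Sex-linked genes had 2 measured members, too few to test, and 0 passed. In untreated 14-day muscle oxidative phosphorylation genes were shifted upward in the knockout with 0 of 55 past the threshold in limma (camera adjusted p = 0.00171 and adjusted p = 0.772 with an estimated correlation).

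The first pattern weighed was that of genotype calls near Trim63, where of 180 tested genes within 300 genes of Trim63, 13 were called in at least one genotype comparison, or 7.22%, against 14 of 467 farther away on its chromosome, or 3%. On other chromosomes 102 of 10344 were called, or 0.986%, a ratio of shares of 7.32 (Fisher's exact p = 7.43e-08). DNA of another mouse strain around the knockout allele predicts such a ratio and may account for it, but the labels give C57/Bl6 for all mice, and the origin and backcrossing of the allele are not given in the sources used here. An effect of the altered locus on its nearest genes does not predict the spread. Of the 13, 7.69%, or 1, lay within 10 genes of Trim63. This was Slc30a2, next to Trim63 in gene order. It was higher by 1.81 and 2.19 under dexamethasone and did not pass untreated, at 0.54 and 0.84. For Slc30a2 itself such an effect was left open. The farthest of the 13, Zmym6, lay 244 genes away, within a window that ends at 300. Beyond it Cap1, Hyi and Rbp7 (at -374, -499 and 464 genes) were higher and Ube4b (at 462) lower in all 4 comparisons. Sequence differences under single probes could not be decided, as 0 of the 2 called genes with another probe, Eya3 and Myom3, were shown by it.

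Clock genes called between genotypes in untreated 14-day muscle, Per2, Dbp and Ciart, were weighed next. Their median difference between knockout and wild type was 1.49 at 14 days and -0.28 at 3 days, which goes against an effect of the knockout by itself. Of the 11 measured clock genes not called between genotypes, 3 differed between the untreated arms in wild type, against 23 of 16248 other features (Fisher's exact p = 5.94e-07, with genes taken as independent, which clock genes are not), and 0 in the knockout. Wild-type untreated mice of the 14-day arm at another clock phase may thus account for the pattern, although the same wild-type arrays enter both comparisons. Times of day are not given in the sources used here.

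Epidermal genes lower in treated 14-day knockout muscle, Lor at -5.24, Lce1m at -3.62, Lce1b at -2.71 and Lgals7 at -2.65, were weighed last. Deviations of 39 measured keratinocyte markers, a list added after the data were seen, from their group means correlated at 0.534 on average, against at most 0.105 in 1000 random lists. Skin carried along with some muscles predicts this and may account for it. Any genes that vary together would exceed random lists, however, and slow fibre genes had an estimated correlation of 0.536. The list also holds the genes named above, so the test cannot tell skin from another shared cause. Knockout arrays lay above the wild-type mean of these markers in 1 of 12 cases, and the marker median was lower in the knockout in 3 of the 4 genotype comparisons (-0.653 in treated and -0.625 in untreated 14-day muscle, -0.279 in untreated 3-day muscle) and higher in treated 3-day muscle (0.189), which leaves an effect of genotype undecided. Lor had a log2 signal of 4.63 ± 0.37 in treated 14-day knockout and 9.87 ± 1.31 in treated 14-day wild type (SD, n = 3 each). Lce1m and Lce1b are near-identical copies, so their probes are not separate measurements.

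Probes without a gene symbol also differed by genotype. ILMN_2417556 was higher in the knockout by between 6.03 and 7.65 and ILMN_1215654 lower by between -4.84 and -6.50 in the 4 genotype comparisons (log2), and both were chosen after their values were seen. Among named genes outside the window around Trim63, Cap1, Haus1, Hyi, Paip1, Rab4a and Rbp7 were higher and Gatad2a, Rab6b, Ube4b, Xirp2 and Zfp131 lower in all 4 comparisons. Of these, Cap1, Hyi, Rbp7 and Ube4b lie on the chromosome of Trim63.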
